A study of Mus musculus with 2 samples.

How the data were processed

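Single-cell RNA sequencing was done on dissociated whole intestine of 2 mice. One library came from a mouse with collagen-induced arthritis on standard chow, called the RA library here, and 1 from a mouse on a diet with 1% butyrate, called the butyrate library. The labels do not say whether the butyrate-fed mouse also had arthritis. Libraries were made with droplet 3' chemistry, and the deposited tables hold raw UMI counts per gene and cell barcode, with no normalization. Per the labels, the authors used Cell Ranger 6.0.1 and Seurat 4.0.3 and 4.0.4 with the mm10 genome. The headers of the deposited count tables name Cell Ranger 7.1.0 instead, and whether intronic reads were counted is not stated. Gene identifiers were matched to GENCODE M21 on GRCm38, the build that mm10 names: 31107 of the 31253 identifiers were found there.

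Barcodes with at least 500 UMIs, at least 250 genes and at most 25% mitochondrial UMIs were kept. Doublet scores were computed with Scrublet in scanpy 1.11.5. The tool's own threshold marked 0 doublets in both libraries (thresholds of 0.615 and 0.669), so barcodes with the highest scores were removed up to the expected share of 0.8% per 1000 barcodes. This removed 382 RA and 544 butyrate barcodes. Counts of both libraries together were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were reduced to 30 principal components, joined by 15 nearest neighbours and clustered with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with no batch correction, since library and group coincide. Of the resulting clusters, 42 held at least 10 cells, after 2 mixed clusters had been split again.

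Clusters were named from 343 markers of 33 cell classes, 338 of them in the files. A marker counted as detected in a cluster when at least 10% of the cells had a UMI and its level was at least 2-fold above the mean of the other clusters, after 10 CPM had been added to both. A name needed 3 detected markers, and among such classes the one with the highest mean log2 fold of its markers was taken. The name was withheld where another class had more markers among the 10 leading genes. It was also withheld from clusters of low depth without a marker of the class among those genes. Names are written "-like" because they rest on these markers alone. Classes were grouped into compartments.

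With 1 library per group there is no replicate, so no test between the groups was made, no p-value is given and no genes were counted as changed. Shares carry exact Clopper-Pearson 95% intervals, and beside a count of 0 the limit given is instead 3 counts of the total, about a one-sided 95% limit. Within each class the UMIs of each gene were summed per library and expressed as CPM of the class total, with exact Poisson 95% intervals. Ratios are butyrate over RA, with the exact conditional binomial 95% interval. These intervals cover counting error only. A ratio against 0 UMIs is given as a lower bound against a floor of 3 counts over the class. Classes with at least 100 kept cells in each library were compared, at most 8. Their summed depth ranged from 1080635 to 20829539 UMIs.

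Before the data were examined, 30 gene lists with 441 members were fixed, 439 of them in the files, together with the class markers, the comparisons and most alternatives. A list's median log2 ratio over members with at least 20 UMIs (at least 5 members, with 0.5 added to each sum) was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The central 95% of the random medians is called the random range. It describes these 2 libraries and is no test between diets. Of 151 pairs of list and class, 137 had enough members.

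Genes were named by a rule fixed in advance. In each compared class these were the 3 highest and 3 lowest ratios among genes with at least 50 UMIs and an interval excluding 1. Mitochondrial, ribosomal protein, immunoglobulin and T cell receptor segment, hemoglobin, Y-linked, Xist and unnamed gene models were left out. So were genes that in both libraries lay far below their level in the class that expresses them most. That comparison guards against free RNA but does not measure it. In list results, such genes are said to lie far below their level in another class. The rule added up to 4 members with the farthest ratios per list, in the class where the list's median lay farthest from its random range, and the 3 most abundant markers per class. The text gives the leading ones. Results of 3 genes, among them 1 counted for lineage, are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Several named genes also lead a cluster of their own class, so their values were recomputed over the whole compartment.

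T and innate lymphoid cells with a UMI of a lineage gene were counted after each cell was thinned to 1000 UMIs, beside the same share in epithelial cells as background. Heavy chain classes were given as shares of constant-region heavy chain UMIs. Free RNA was estimated per class and library from genes that the class should lack, at 1.8% to 8.85% of UMIs. Its profile was taken as the sum of all kept cells of the library.

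Alternatives changed 1 choice at a time. For shares these were a 10% or no mitochondrial limit, a minimum of 1000 UMIs, doublets kept, resolutions of 0.5 and 2, each library clustered on its own, each cell assigned on its own, shares within a compartment, and a UMI floor common to both libraries. For expression they were TMM (edgeR 4.0.16), DESeq2 1.42.0 size factors, the mean over cells scaled to 10000 UMIs, cells thinned to 1000 UMIs, the 10% mitochondrial limit, the minimum of 1000 UMIs, totals without abundant gene families, subtraction of free RNA, clusters weighted alike, and no minimum or a minimum of 100 UMIs per list member. Random ranges under alternatives rest on 2000 random lists. TMM and DESeq2 moved the median of all genes by 0.13 on the log2 scale in goblet-like cells, and by 0.11 and 0.12 in germinal centre B cell-like cells, and by less than 0.1 in the other classes. Random ranges carry the same shift, so lists are read against them. The common UMI floor, the clusters weighted alike and the subtraction of free RNA for lists were chosen after seeing the data.

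The method was tested on simulated data, Poisson counts with known folds at the depth of a small and a large class. The 95% interval held the true ratio in 95.8% and 95.7% of genes simulated without a fold. A 2-fold higher level gave an interval above 1 in 97.1% of genes in both, and a 2-fold lower level one below 1 in 84.0% and 100.0%. At 1.5-fold these were 70.6% and 85.3% for a higher and 46.4% and 78.1% for a lower level, so ratios of that size are often missed in a small class. The interval assumes the same Poisson model, so its coverage was set by design and only checks the computation. Real UMIs of a gene can come from few cells. There the intervals are too narrow, and the simulated rates do not carry over. Lists of 12 genes without a fold fell outside the random range in 3.0% of draws. The simulated genes vary independently, so this rate does not carry over to real lists, whose members may move together. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3, were used.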

Results

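Cells of the whole intestine were profiled in 2 libraries, 1 from a mouse with collagen-induced arthritis on standard chow (RA) and 1 from a mouse on a diet with 1% butyrate. Butyrate is a short-chain fatty acid that gut bacteria make from fibre and that colonocytes burn as fuel. The RA library held 10140 barcodes with 61912439 UMIs, and the butyrate library 9959 barcodes with 67894477 UMIs. After filtering, 6527 RA cells with a median of 4670.0 UMIs and 7703 butyrate cells with a median of 5062 UMIs were kept. The lowest barcode had 501 UMIs in the RA library and 2313 in the butyrate library. Above the mitochondrial limit lay 29.95% of the RA barcodes and 15.42% of the butyrate barcodes. No replicate mouse exists for either group, so each difference below compares 1 animal with 1 animal, and its interval covers counting error only.

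The first comparison asks which cell populations differed in size between the arthritic mouse on chow and the butyrate-fed mouse. Lymphocytes made up a larger share of the butyrate library. T cell-like cells were 11.6% of it (95% interval 10.9% to 12.4%) against 6.16% of the RA library (5.59% to 6.77%), a ratio of 1.89 (1.68 to 2.13), or 1.27 (1.125 to 1.43) among T and innate lymphoid cells alone. Germinal centre B cell-like cells, in which B cells mutate and select their receptors, were 3.58% against 1.99%, a ratio of 1.80 (1.46 to 2.23). No cluster took this name at resolution 0.5, and none of the RA library did when each library was clustered on its own. B cell-like cells were 54.9% against 46.1% (ratio 1.19, 1.14 to 1.25). Plasma cell-like cells, the antibody-secreting end of the lineage, went the other way, at 1.21% against 2.34% (ratio 0.515, 0.394 to 0.671).

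Stromal and myeloid cells made up smaller shares of the butyrate library. Dissociation and loading also set such shares, and cells of fat and of the outer gut surface, described below, were likewise fewer there. Fibroblast-like cells were 4.14% of it against 12.2% of the RA library (ratio 0.340, 0.297 to 0.387), and lymphatic endothelial-like cells 0.312% against 1.39% (ratio 0.224, 0.136 to 0.354), or 0.432 with each cell assigned on its own. Among stromal cells alone the fibroblast-like and lymphatic endothelial-like ratios were 0.932 and 0.613. Macrophage or monocyte-like cells were 1.58% against 3.39% (ratio 0.468, 0.372 to 0.586). Among myeloid cells alone their ratio was 1.22. Eosinophil-like cells were 0.195% against 2.05% (ratio 0.0949, 0.0516 to 0.162), or 1.67% against 2.41% (ratio 0.696) with each cell assigned on its own. Of the 134 RA cells named by cluster, 130 lay below the lowest UMI number of the butyrate library. With at least 1000 UMIs the ratio was 0.305, and with this lowest number as the floor in both libraries it turned to 2.85 (0.908 to 11.8), on 4 and 15 cells. Median depth of eosinophil-like cells was 772.5 UMIs in the RA and 4873 in the butyrate library. Whether both sets are the same kind of cell was not tested.

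The epithelium as a whole took 12.3% and 13.0% (ratio 0.9495, 0.865 to 1.04), but 4.65% and 6.31% (0.737) with a 10% mitochondrial limit and 21.2% and 25.5% (0.833) without a limit. Colonocyte-like cells were 9.62% of the butyrate cells and 8.84% of the RA cells (ratio 1.09, 0.975 to 1.22), and goblet-like cells, which make mucus, 1.88% and 2.88% (ratio 0.654, 0.523 to 0.816). Of the 188 RA goblet-like cells 63 lay below the lowest UMI number of the butyrate library, and with that floor in both libraries the ratio was 0.881 (0.689 to 1.13). The colonocyte-like ratio was 0.763 with a 10% mitochondrial limit and 2.05 when each library was clustered on its own. CD8 or intraepithelial T cell-like cells were 4.02% and 3.51% (ratio 1.15, 0.964 to 1.37), a ratio that was 0.275 when each library was clustered on its own and 0.769 (0.646 to 0.916) among T and innate lymphoid cells alone. Regulatory T cell-like cells took 0.948% and 0.935% (ratio 1.01, 0.712 to 1.45), but 4.86% and 7.15% of T and innate lymphoid cells (0.680, 0.477 to 0.971). Group 3 innate lymphoid-like cells, a source of interleukin 22, took 1.49% and 1.30% (ratio 1.15, 0.859 to 1.54), or 0.768 (0.576 to 1.03) within that compartment.

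**Figure D1:**
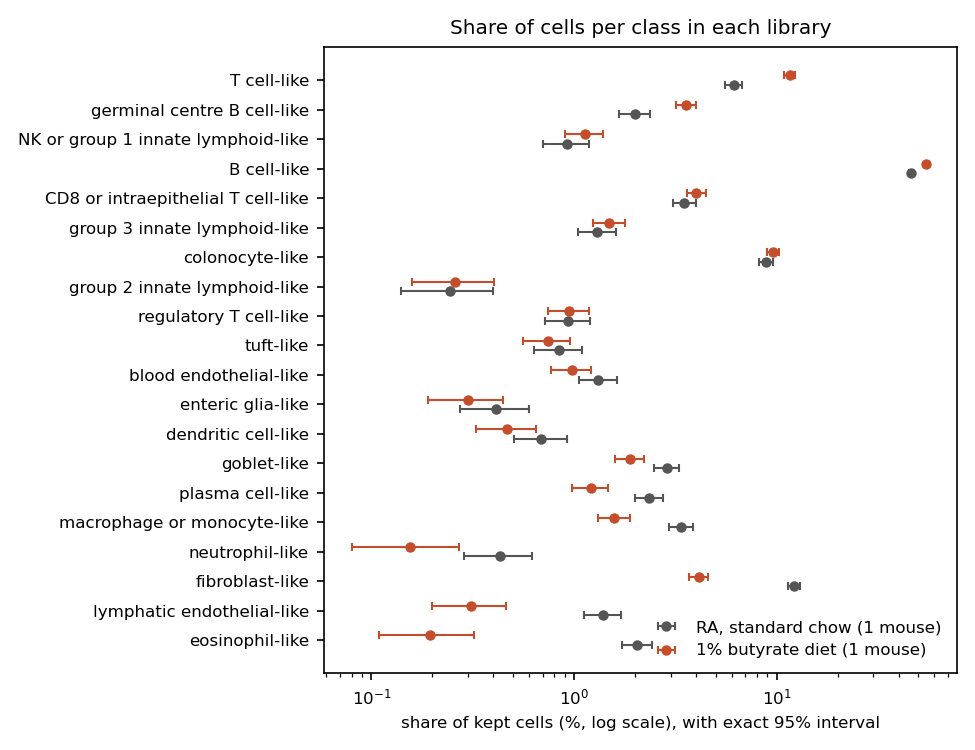
Share of kept cells per class in percent on a log axis, in the RA library (grey) and the butyrate library (orange), 1 mouse each. Points are shares and bars exact 95% intervals, for classes with at least 10 cells in each library. T cell-like cells lie at 6.16% and 11.6%, fibroblast-like cells at 12.2% and 4.14%.

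The second comparison asks how gene expression in the epithelium differed between the 2 mice, starting with colonocyte-like cells. Interferon-induced genes were higher in the butyrate library. All 18 measured members of the type I interferon list were higher, with a median log2 ratio of 1.11 (random range -0.09 to 0.13). Ifit2, an interferon-induced RNA-binding protein (chromosome 19, 34550694 to 34576419), had 71.0 against 16.4 CPM, a ratio of 4.32 (3.61 to 5.20). Ifit1 (chromosome 19, 34640871 to 34650009) had 159.5 against 46.5 CPM (ratio 3.43, 3.08 to 3.84). The antiviral Rsad2 and the deconjugase Usp18 had ratios of 3.28 and 3.04. With a 10% mitochondrial limit the ratio of Ifit2 was 12.1, and with cells thinned to 1000 UMIs that of Rsad2 was 1.94.

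Genes that present antigen on MHC class I moved the same way, with 11 of 12 members higher (median 0.64, random range -0.13 to 0.17). H2-K1, an MHC class I heavy chain, had a ratio of 1.89 (1.83 to 1.94), its partner B2m one of 1.82 (1.77 to 1.86), and Nlrc5, the transactivator of these genes, one of 1.88 (1.55 to 2.30). In the interferon gamma list 17 of 18 members were higher (median 0.63, range -0.24 to 0.12), among them the checkpoint ligand Cd274 at 2.64 and the GTPase genes Irgm2 at 2.53 and Gbp3 at 2.05. With cells thinned Cd274 stood at 1.36, and with the 10% limit Irgm2 at 1.43. Of these 18 genes, 14 lay far below their level in another class, where free RNA can contribute. The MHC class II median of 0.16 barely passed its range of -0.26 to 0.16, and was -0.003 with clusters weighted alike.

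Fuel and lipid genes of colonocyte-like cells differed as well. In fatty acid oxidation and ketogenesis 17 of 22 members were higher (median 0.33, random range -0.09 to 0.13). Pdk4, a kinase that shuts pyruvate out of the mitochondrial fuel supply (chromosome 6, 5483351 to 5496309), had 106.2 against 26.7 CPM, a ratio of 3.97 (3.45 to 4.595). The thioesterase Acot1 had a ratio of 1.87 (1.41 to 2.495). Of the cholesterol synthesis genes 15 of 18 were lower (median -0.31, range -0.13 to 0.12), including Fdps at 0.581 (0.493 to 0.682), Idi1 at 0.612 and Fdft1 at 0.624. Both medians came inside the random range when cells were thinned to 1000 UMIs, at 0.18 and -0.25, while Pdk4 stood at 7.099 and Fdft1 at 0.389.

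Lists tied to butyrate uptake and the barrier stayed inside their random ranges in colonocyte-like cells. The short-chain fatty acid transporters and receptors had a median of 0.12 with 5 of 6 members higher, and tight junctions one of 0.15 with 9 of 14 higher, led by the junction proteins Marveld3 at 1.29 and Cgn at 1.26. Lipid absorption and chylomicron assembly had 0.15 with 6 of 11 higher, among them Fabp2 at 1.53 and Apob at 1.52, while the lipoprotein receptor Scarb1 was at 0.633. Retinoic acid metabolism had 0.12 with 4 of 6 higher, from Isx at 1.45 to Lrat at 0.610 (0.188 with cells thinned). Fabp2 leads a cluster of this class, and over the whole epithelium its ratio was 1.56. Of the colonocyte markers, the water channel Aqp8 had 1105 against 742.7 CPM and the acute phase gene Saa1 1838 against 2184 CPM.

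The lowest ratios in colonocyte-like cells belonged to Reg3b and Reg3g, secreted lectins that act against gut bacteria. Reg3b (chromosome 6, 78370657 to 78373466) had 30.8 against 2191 CPM, a ratio of 0.0141 (0.0125 to 0.0158), or 71.0-fold lower. Reg3g (chromosome 6, 78466269 to 78468872) had 16.9 against 462.9 CPM, a ratio of 0.0366 (0.0310 to 0.0429), or 0.0156 with the 10% mitochondrial limit and 0.0590 as a mean over cells. In the RA library 118 of 577 cells held a Reg3b UMI, and the top 10 cells held 59.5% of them. In the butyrate library 33 of 741 cells held one. Reg3b leads 1 of the clusters of this class, and over the whole epithelium its ratio was 0.0144 (0.0128 to 0.0162). In the other colonocyte-like cluster, which it does not lead, it had 39.1 against 1580.0 CPM.

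The antimicrobial list as a whole went the other way, with 11 of 16 members higher and a median of 0.26 (random range -0.13 to 0.14). The mucus list had 8 of 12 higher (median 0.34, range -0.14 to 0.15), 9 of the 12 far below their level in another class. Both medians came inside the range on thinning, at 0.095 and 0.18. Cell cycle genes were lower in 17 of 18 cases (median -0.62, range -0.23 to 0.10). Stem and transit amplifying cells had no cluster of their own name, and their number within this class was not examined. Heat shock genes were higher in 12 of 12 (median 0.71, range -0.12 to 0.18), and immediate early and dissociation genes in 14 of 17 (median 0.21, range -0.11 to 0.15). The immediate early median was -0.069 with cells thinned. Creb3l3, a transcription factor of lipid metabolism, had a ratio of 5.83 (3.14 to 11.8) on 72 and 12 UMIs, and Patl2 one of 6.44 (3.04 to 15.7). They moved to 2.95 and 15.2 as means over cells, and to 11.3 and 3.75 on thinning. Krt16 had a ratio of 11.4, but 42 of its 47 butyrate UMIs came from 1 cell, and 32 of the 49 RA UMIs of Ptprq, at 0.0992, did too. On thinning Ptprq stood at 1.501.

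Goblet-like cells of the butyrate library held more RNA of several mucus and defence products and less of Reg3b and Reg3g. In the mucus list 11 of 13 members were higher (median 0.46, random range -0.25 to 0.13). Retnlb, a bactericidal goblet cell protein (chromosome 16, 48816856 to 48818892), had 9264 against 1832 CPM, a ratio of 5.06 (4.90 to 5.22). Clca1, a protease that remodels mucus (chromosome 3, 145003817 to 145032776), had 12050.0 against 3183 CPM (ratio 3.79, 3.69 to 3.88), and Fcgbp, a mucus scaffold protein, a ratio of 2.45. Ang4, an antimicrobial ribonuclease, had a ratio of 4.70 (4.56 to 4.84), and the antimicrobial list had 10 of 14 higher (median 0.48, range -0.29 to 0.11). Reg3b and Reg3g, of the same list, had 137 and 112 RA UMIs but 1 butyrate UMI each, ratios of 0.00780 (0.000196 to 0.0442) and 0.00955 (0.000240 to 0.0543). Single RA cells held 73 and 97 of these UMIs, and on thinning Reg3g stood at 0.266. Retnlb, Clca1, Fcgbp and Ang4 lead clusters of this class. Over the whole epithelium their ratios were 4.65, 3.41, 2.19 and 4.27, and as means over scaled goblet-like cells 2.29, 2.06, 1.37 and 2.37. Muc2, the main gel-forming mucin, had a ratio of 1.53 (1.51 to 1.56).

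Folding and stress genes of the secretory pathway were higher too. The unfolded protein response list had 13 of 13 members higher (median 0.53, random range -0.28 to 0.13), among them the chaperones Sdf2l1 at 2.01 (1.55 to 2.62) and Hyou1 at 1.98, although the median came inside the range on thinning, at 0.16. The heat shock median was 0.27 and the immediate early median 0.15, both above their ranges. Type I interferon genes were higher in 15 of 16 cases (median 0.52), MHC class I in 11 of 12 (0.77), interferon gamma in 11 of 12 (0.89) and MHC class II in 6 of 8 (0.85), with Cd74, the invariant chain, at 2.41 (2.14 to 2.73). The interferon gamma and MHC class II genes all lay far below their level in another class, where free RNA can contribute. On thinning the type I interferon median was 0.087, inside its range. Cd74 had a ratio of 15.3 after subtraction of free RNA. For such genes little may be left after that step, so this ratio is unstable and does not measure a difference. With clusters weighted alike the MHC class II median was 0.34 (range -0.50 to 0.21).

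Genes of dividing cells were lower in goblet-like cells, and so was the stem cell receptor Lgr5. The cell cycle list had 17 of 17 members lower (median -1.36, random range -0.41 to 0.10), with the topoisomerase Top2a at 0.325 (0.177 to 0.567), Birc5 at 0.386 and Ube2c at 0.361. A cluster led by Mptx1 and Itln1 held 37.8% of these cells in the RA library and 21.4% in the butyrate library. With clusters weighted alike the median was -0.59 (range -0.45 to 0.12), Birc5 stood at 0.704, Ube2c at 0.723 and Cdk1, at 0.380 before, at 0.9895. Clusters were weighted there by their share of cells, whereas the reported ratios sum UMIs. The weighting therefore changes more than the make-up of the class. As means over cells Birc5 and Ube2c stood at 0.830 and 0.835, and Ube2c at 1.06 with cells thinned. Lgr5 had 1 against 78 UMIs, a ratio of 0.0137 (0.000343 to 0.0786), with the RA UMIs in 14 cells. No cluster took the name of stem and transit amplifying cells, so such cells may lie within the goblet-like class. How many did in each library was not examined. Cholesterol synthesis was lower in 18 of 18 genes (median -0.48, range -0.30 to 0.07), and fatty acid oxidation higher in 15 of 20 (0.20, range -0.25 to 0.06). Short-chain fatty acid transporters and receptors (-0.29), with the butyrate receptor Ffar2 at 0.758 (0.633 to 0.907), tight junctions (-0.06) and lipid absorption (0.14) lay inside their ranges. The lipase gene Pnliprp2 had a ratio of 7.14 (4.55 to 11.8). All 261 butyrate UMIs of the hormone gene Sst, at least 93.0-fold higher, came from 1 cell.

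**Figure D2:**
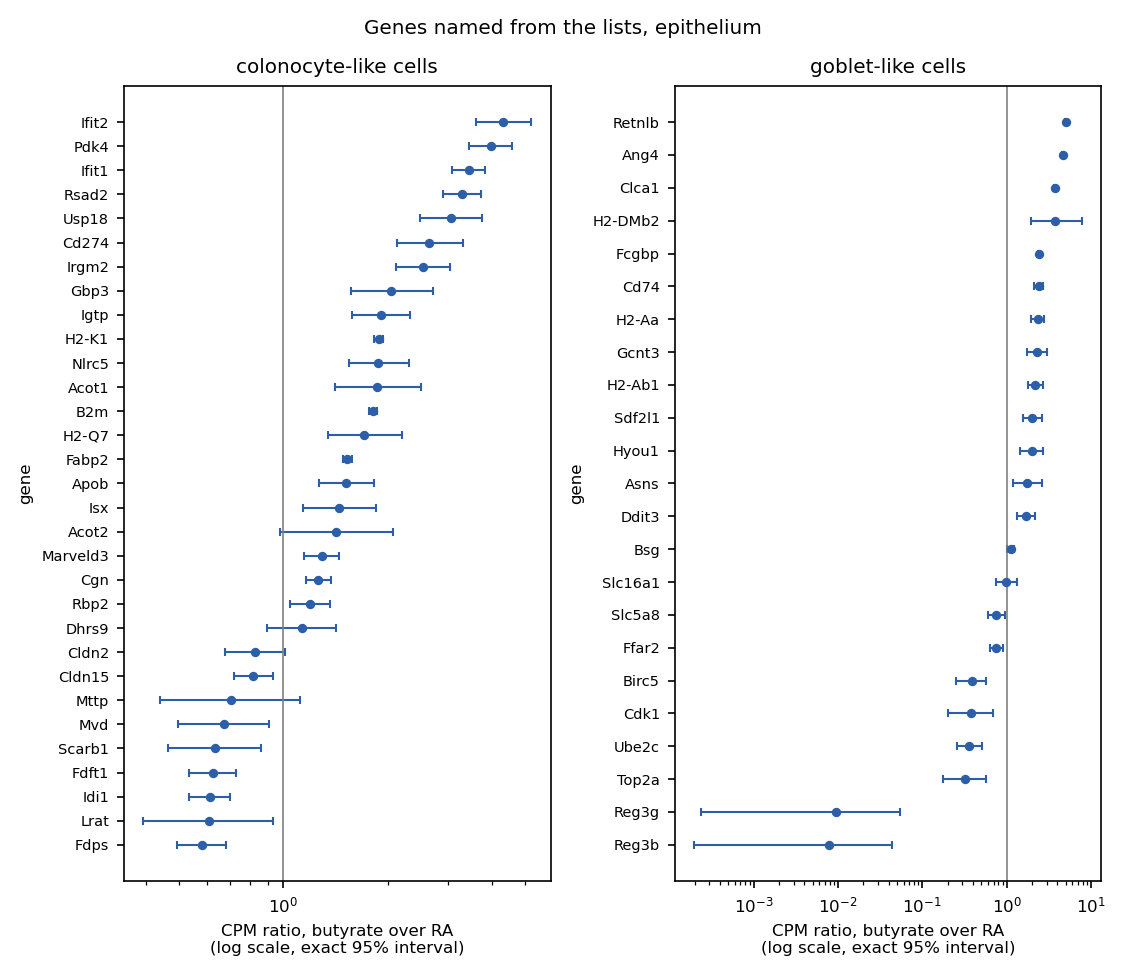
Ratio of CPM, butyrate over RA, on a log axis for most genes named from the lists in colonocyte-like cells (left) and goblet-like cells (right), 1 mouse per group. Points are ratios, bars exact 95% intervals, and the grey line marks a ratio of 1. Ifit2 lies at 4.32 and Fdps at 0.581 on the left, Retnlb at 5.06 and Reg3b at 0.00780 on the right.

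The third comparison asks how lymphocytes of the gut differed. T cell-like cells of the butyrate library held more interferon-induced RNA. Of the type I interferon list 16 of 17 members were higher (median 0.60, random range -0.21 to 0.16), and of the interferon gamma list 15 of 16 (0.58, range -0.19 to 0.14). Of these, 14 of the 17 and 11 of the 16 lay far below their level in another class, where free RNA can contribute. MHC class I was higher in 11 of 12 genes (0.20, range -0.16 to 0.12). The T helper 17 list lay below its range at -0.42 (range -0.31 to 0.25), with 5 of 10 members higher and 5 lower, and 8 of the 10 far below their level in another class. The interleukin 1 receptor Il1r1 had a ratio of 1.76 (1.16 to 2.74) and the chemokine receptor Ccr6, the least lowered of the 5, one of 0.564 (0.313 to 1.03). On thinning these stood at 3.98 and 0.295. The other 4 lower members, named after their values were seen, had few UMIs and intervals below 1: Il17a (0.0126, on 34 RA UMIs and 1 butyrate UMI), Ccl20 (0.0357), Il17f (0.0714) and Il22 (0.339). How many cells held these UMIs was not examined. Across all T and innate lymphoid cells, unthinned, 52 of 1502 butyrate and 42 of 853 RA cells had an Il17a UMI (ratio 0.703, 0.459 to 1.08). For Il22 that ratio was 0.707 (0.477 to 1.05). The T helper 17 median was -0.29 and inside the range with clusters weighted alike, but -1.03 without a UMI minimum and -0.77 after subtraction of free RNA, both below it. The follicular helper list stood at 0.19 (range -0.24 to 0.17) with 6 of 10 higher, and at -0.016 with clusters weighted alike. T helper 1 and cytotoxic genes (0.11), regulatory T cell and interleukin 10 genes (-0.06), and NF-kB and inflammatory cytokines (0.10) lay inside their ranges. MHC class II genes, which mouse T cells hardly express, had a median of -0.78, with all 9 measured members far below their level in another class. Heat shock genes (-0.04) and immediate early genes (0.04) lay inside their ranges.

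CD8 or intraepithelial T cell-like cells had less RNA of the granzyme genes Gzma and Gzmb and more of Ifng. Gzma, granzyme A (chromosome 13, 113093825 to 113100981), had 363.3 against 2113 CPM, a ratio of 0.172 (0.1596 to 0.185). Gzmb, granzyme B, had a ratio of 0.514 (0.490 to 0.539) and the chemokine Ccl5 one of 0.538 (0.526 to 0.551). These genes lead clusters of this class, and over all T and innate lymphoid cells their ratios were 0.163, 0.619 and 0.503. Ifng, the cytokine interferon gamma (chromosome 10, 118441046 to 118445892), had 113.8 against 45.1 CPM, a ratio of 2.52 (1.93 to 3.33), with 63 of its 284 butyrate UMIs in 1 cell, and 1.53 with cells thinned. The list of T helper 1 and cytotoxic genes lay inside its range at -0.15 with 7 of 11 lower, as did type I interferon (-0.15), interferon gamma (-0.25), NF-kB (-0.18), and regulatory T cell and interleukin 10 genes (0.20). Immediate early genes were lower in 13 of 17 cases (-0.37, random range -0.15 to 0.21), a median that was -0.076 and inside on thinning. Different clusters held most of this class, with 55.0% of its RA cells in a cluster led by Trdc and Klra5 and 66.1% of its butyrate cells in a cluster led by Cd8a and Nkg7. The sialic acid enzyme gene Cmah had a ratio of 4.67 (2.85 to 8.11; 7.76 with cells thinned), and the ubiquitin ligase gene Peli2 one of 0.311 (0.584 with clusters weighted alike).

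Lineage genes were counted across all T and innate lymphoid cells at equal depth, 847 RA and 1502 butyrate cells. A UMI of Tbx21, the T helper 1 regulator T-bet, was found in 1.40% of butyrate cells against 2.95% of RA cells, a ratio of 0.474 (0.252 to 0.882), and in 8.19% against 10.1% without thinning (0.812, 0.612 to 1.08). Trdc, the delta chain of the gamma delta T cell receptor, was found in 4.39% against 7.08% (ratio 0.620, 0.431 to 0.895). At this depth neither was found in 781 RA and 948 butyrate epithelial cells (up to 0.384% and 0.316%). Without thinning, a Tbx21 UMI was found in 5 of 846 and 3 of 948 epithelial cells, and a Trdc UMI in 0 of 846 (up to 0.355%) and 2 of 948. Cxcr5, the receptor that takes cells into follicles, was found in 2.60% against 0.708% (ratio 3.67, 1.54 to 10.6), while epithelial cells gave a background of 0.949% and 0.512%, which leaves the RA share within background. Its ratio was 2.26 (1.21 to 4.52) with cells thinned to 2000 UMIs and 1.96 (1.36 to 2.89) without thinning, where 8.72% and 4.45% stood against 6.33% and 4.61% of epithelial cells. Intervals of the ratio spanned 1 for Foxp3 (0.831), Gata3 (0.833), Il17a (0.785), Il22 (0.620), Il10 (0.591), Ifng (1.61), Il2ra (0.807), Cd4 (0.940) and Cd8a (0.789). With cells thinned to 2000 UMIs instead, Il22 at 0.572 (0.335 to 0.979) and Il10 at 0.554 (0.331 to 0.926) had intervals below 1, and without thinning neither did. Median depths before thinning were 6024.5 and 5797 UMIs in these cells and 6357 and 7254.5 in epithelial cells.

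Germinal centre B cell-like cells of the butyrate library expressed more proliferation and metabolic genes and less of the germinal centre programme per UMI. Cell cycle genes were higher in 16 of 18 cases (median 0.31, random range -0.16 to 0.15), glycolysis in 10 of 14 (0.20, range -0.22 to 0.17), with Ldha at 1.33 (1.17 to 1.53), and oxidative phosphorylation in 20 of 24 (0.17, range -0.13 to 0.14). Heat shock genes (0.73) and the unfolded protein response (0.42) were above their ranges, the latter at 0.087 and inside on thinning. All 8 members of the follicular helper and germinal centre list were lower (median -0.36, range -0.24 to 0.23), including the death receptor Fas at 0.631 (0.520 to 0.768) and S1pr2, which keeps B cells in the germinal centre, at 0.663 (0.536 to 0.825). All 10 MHC class II genes were lower as well (-0.41, range -0.21 to 0.20), and 6 of 7 NF-kB genes (-0.42). The plasma cell secretory programme stood at 0.17 (range -0.24 to 0.16), and at 0.12 and inside with clusters weighted alike. A cluster led by Mki67 and Top2a held 48.6% of these cells in the butyrate library and 35.4% in the RA library. On thinning the cell cycle (0.253, range -0.22 to 0.256), glycolysis (0.20, range -0.34 to 0.37) and oxidative phosphorylation medians (0.085, range -0.18 to 0.22) lay inside their ranges, which were wider there. The glutathione transferase gene Gstp1 had a ratio of 5.32 (1.99 to 20.01), and Bcat1, which breaks down branched-chain amino acids, one of 3.38 (2.17 to 5.56).

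B cell-like cells had list medians between -0.28 and 0.30. Type I interferon genes had a median of 0.30 (random range -0.22 to 0.09) with 11 of 18 higher. Of the 18, 17 lay far below their level in another class. MHC class I had 0.21 (-0.14 to 0.06) with 12 of 12 higher, and oxidative phosphorylation 0.10 with 18 of 24 higher. Immediate early and dissociation genes stood at 0.13 (-0.14 to 0.05) with 12 of 17 higher. The list of immunoglobulin constant regions and secretion stood at -0.28 (-0.16 to 0.09) with 8 of 12 lower, including Jchain at 0.729, and at 0.00 after subtraction of free RNA. The plasma cell secretory programme lay inside its range at 0.04. Heat shock genes were below theirs (-0.23, range -0.16 to 0.08), and at -0.11 and inside after subtraction. The T helper 17 list stood at 0.19, and at -0.035 without a UMI minimum. Tpd52l1 was the best counted of the lowest genes, with a ratio of 0.430 (0.356 to 0.518). Of the 50 butyrate UMIs of Pyy, the highest at 7.74, 36 came from 1 cell.

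Plasma cell-like cells made mostly IgA in both mice. Igha took 89.8% of heavy chain UMIs in the butyrate library and 97.6% in the RA library (ratio 0.920, 0.912 to 0.927), and it was the most abundant class in 79 of 93 and 145 of 153 cells. The remainder was larger with butyrate. Ighm took 5.21% against 0.148% (ratio 35.2, 31.4 to 39.6) and Ighg1 2.36% against 0.704% (3.35). Counted by cells, Ighm led in 2 butyrate cells and 1 RA cell (ratio 3.29, 0.171 to 194.0) and Ighg1 in 1 and 2 (0.823, 0.0139 to 15.8). How the UMIs of these genes were spread over the cells was not examined, and intervals of UMI shares leave out differences between cells. Ighg2b took 2.01% against 1.42% of UMIs (1.42, 1.34 to 1.5) and led in 10 of 93 against 5 of 153 cells (ratio 3.29, 1.02 to 12.3). Ighg3 took 0.348% against 0.00701% of UMIs (49.6, 29.6 to 89.7), on 15 RA UMIs, and led in 1 of 93 butyrate cells and no RA cell. Ighd went the other way, at 0.0106% against 0.0238% (0.445, 0.201 to 0.886).

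The fourth comparison asks how macrophages and fibroblasts differed. Macrophage or monocyte-like cells of the butyrate library held more RNA of inflammatory mediators. Of the NF-kB and inflammatory cytokine list 11 of 18 were higher (median 0.31, random range -0.20 to 0.14). Ptgs2, the inducible cyclooxygenase, had a ratio of 2.37 (2.12 to 2.66), Il1a one of 1.78, Il1b one of 1.58 (1.51 to 1.66) and the neutrophil attractant Cxcl2 one of 1.46 (1.43 to 1.501). The 7 measured members of the regulatory T cell and interleukin 10 list were lower (-0.47, range -0.42 to 0.26), but only 3 with an interval below 1. Of the 7, 5 lay far below their level in another class, and the list median was inside its range at -0.16 without a UMI minimum. Il10, the anti-inflammatory cytokine, had a ratio of 0.643 (0.510 to 0.808), while Nrp1 at 0.650 and Ctla4 at 0.845 stood at 1.21 and 1.66 on thinning. Scavenger and complement genes lay inside their range (-0.02), while the mannose receptor Mrc1 stood at 0.604 (0.551 to 0.662) and the lectin Cd209f at 0.357 (0.742 as a mean over cells). Type I interferon genes (0.56), interferon gamma genes (0.40) and heat shock genes (0.69, 12 of 12 higher) were above their ranges, as were MHC class I (0.21), immediate early genes (0.18) and the unfolded protein response (0.25). Cxcl2 and Mrc1 lead a cluster of this class, and over all myeloid cells their ratios were 1.36 and 0.581. Of the histone deacetylases, the enzymes that butyrate inhibits, Hdac9 stood at 0.480 (0.357 to 0.639) and Hdac1 at 1.48 (1.02 to 2.16). The highest ratios rested on few cells: 35 of 61 butyrate UMIs of Il18bp and 53 of 131 of Pla2g2d came from 1 cell each. As means over cells their ratios of 9.14 and 6.04 were 2.52 and 1.32, and on thinning 1.66 and 13.25.

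Fibroblast-like cells of the butyrate library held more heat shock and matrix RNA. All 12 heat shock genes were higher (median 0.89, random range -0.16 to 0.12). Hspb1, a small heat shock protein (chromosome 5, 135887919 to 135889563), had 720.6 against 199.8 CPM, a ratio of 3.61 (3.35 to 3.88), and the chaperones Dnajb1 and Hspa1b had ratios of 2.15 and 1.92. Immediate early genes followed in 15 of 17 cases (0.30), with Fos at 1.52 (1.48 to 1.55) and Atf3 at 1.56. Extracellular matrix genes were higher in 13 of 18 cases (0.20, range -0.14 to 0.10), among them the collagen Col3a1 at 1.37 (1.35 to 1.40), Timp1 at 1.36 and Postn at 1.31. Type I interferon genes were higher in 16 of 16 cases (0.42), MHC class I in 12 of 12 (0.50) and interferon gamma genes in 16 of 17 (0.54). A cluster led by Has1 and Col14a1 held 57.5% of these cells in the RA library and 46.4% in the butyrate library, and a cluster led by Cxcl13 and Postn 37.1% and 48.9%. Over the whole stroma the ratio of Postn was 1.22. The genes at the ends of the ratios rested on few UMIs: 48 of the 102 butyrate UMIs of Ak8, at 10.2, and 59 of the 66 RA UMIs of Ak9, at 0.0363, came from 1 cell.

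Of the 137 list medians, 50 lay above and 22 below the random range. Across the 8 compared classes, the type I interferon, interferon gamma and MHC class I medians each lay above the random range in 6, and heat shock in 5. Mitochondrially encoded genes lay below it in 7, all but colonocyte-like cells, with medians from -0.53 in CD8 or intraepithelial T cell-like cells, where all 13 genes were lower, to -0.22. Histone deacetylases lay inside the range in 8 of 8 classes, with medians from -0.37 to 0.05. Aryl hydrocarbon receptor targets had at most 3 measured members in any class and no median was taken.

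**Figure D3:**
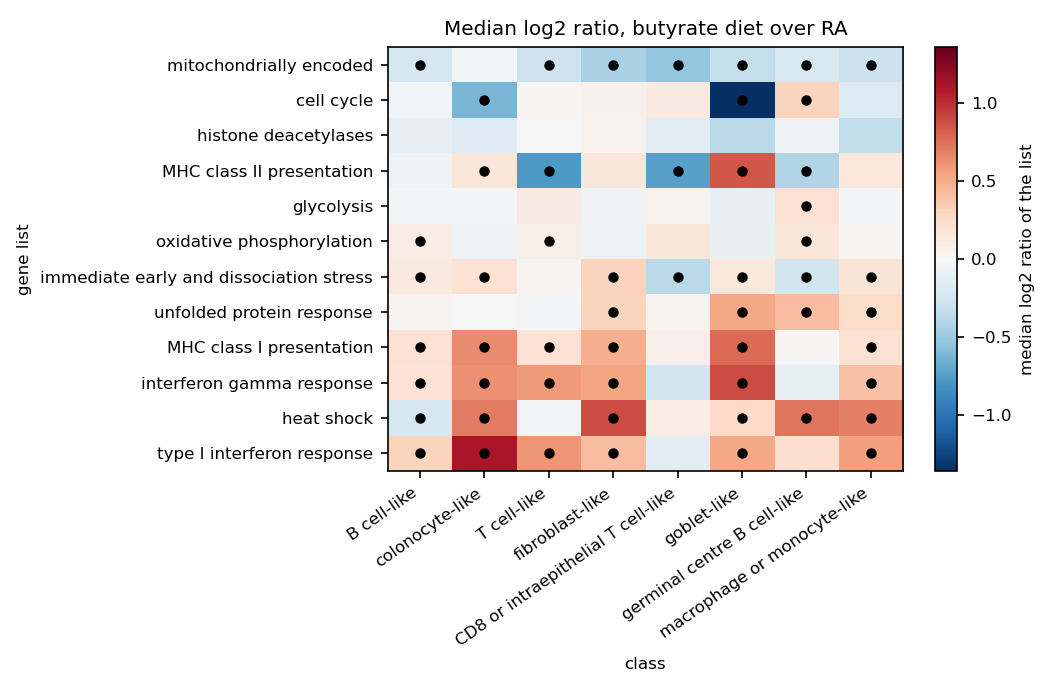
Median log2 ratio, butyrate over RA, of each gene list measured in all 8 compared classes (columns), 1 mouse per group. Red is higher and blue lower in the butyrate library, and a dot marks a median outside the central 95% of random lists. The type I interferon median reaches 1.11 in colonocyte-like cells, and the cell cycle median -1.36 in goblet-like cells.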

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

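The common UMI floor, the weighting of clusters alike and the subtraction of free RNA for lists were tests chosen after the data had been seen. No paired analysis was possible because there was 1 mouse per group. Of 239 class shares recomputed under an alternative, 202 stayed within the 95% interval of the reported ratio, 35 moved out of it and 2, both with a reported interval excluding 1, changed direction. Among the first 2 groups, 24 whose reported interval spans 1 crossed 1 as well. Of 25 compartment shares 6 moved, of 892 list medians 58 moved, and of 1399 gene ratios 236 moved. Of values outside the random range or with an interval excluding 1, 5 list medians and 9 gene ratios changed direction, as did 67 medians inside the range and 12 gene ratios with an interval spanning 1. Of the lineage gene ratios 26 of 26 stayed within the interval, although Il22 and Il10 excluded 1 with cells thinned to 2000 UMIs and Tbx21 spanned it without thinning. Among list medians scaling changed few calls: under TMM 50 of 50 medians above the random range and 22 of 22 below it stayed on their side, although TMM moved 12 and DESeq2 size factors 11 of 160 gene ratios, against 2 of 160 with a minimum of 1000 UMIs. Thinning cells to 1000 UMIs changed more. There 28 of 47 medians above the random range and 10 of 16 below it stayed on their side. Thinning also gives each cell the same weight, so depth alone was not tested. Some classes got no value where clustering was repeated, because no cluster of 1 or both libraries took their name. With each library clustered on its own, germinal centre B cell-like cells numbered 0 in the RA and 274 in the butyrate library. Regulatory T cell-like cells numbered 0 and 93 there, and enteroendocrine-like cells 27 and 0. Lists with too few members and genes without UMIs after thinning, subtraction or weighting got none. The cause was not tested for any value below, except that the share within a compartment changes the denominator and the common floor removes small cells.

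For shares, the ratios that moved were these. Without a mitochondrial limit they were 1.28 for B cell-like cells, 0.854 for colonocyte-like cells, 1.27 for the B lineage and 0.833 for the epithelium. With a 10% limit they were 0.763 for colonocyte-like cells and 0.737 for the epithelium. With at least 1000 UMIs they were 0.305 for eosinophil-like cells and 0.4999 for myeloid cells. Doublets kept gave 1.24 and resolution 0.5 gave 1.26 for colonocyte-like cells. Each library clustered on its own gave 0.275 for CD8 or intraepithelial T cell-like, 2.37 for T cell-like, 2.05 for colonocyte-like and 0.132 for dendritic cell-like cells. Each cell assigned on its own gave 1.13 for B cell-like, 1.24 for colonocyte-like, 0.696 for eosinophil-like, 0.700 for plasma cell-like, 1.18 for dendritic cell-like, 0.434 for enteroendocrine-like, 0.432 for lymphatic endothelial-like and 4.0 for mast cell-like cells. The common UMI floor gave 1.13 for B cell-like cells, 1.13 for the B lineage, 0.881 for goblet-like, 0.543 for enteroendocrine-like and 0.598 for macrophage or monocyte-like cells, 0.649 for myeloid cells and, reversed, 2.85 for eosinophil-like cells. Within the same compartment the ratios were 1.01 for B cell-like, 0.769 for CD8 or intraepithelial T cell-like, 1.27 for T cell-like, 0.247 for eosinophil-like, 0.932 for fibroblast-like, 0.824 for NK or group 1 innate lymphoid-like, 2.03 for blood endothelial-like, 1.76 for dendritic cell-like, 1.98 for enteric glia-like, 0.768 for group 3 innate lymphoid-like, 0.613 for lymphatic endothelial-like, 0.945 for neutrophil-like and 0.680 for regulatory T cell-like cells and, reversed, 1.22 for macrophage or monocyte-like cells.

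With cells thinned to 1000 UMIs, colonocyte-like medians were 0.18 for fatty acid oxidation, 0.18 for mucus, 0.095 for antimicrobial products, 0.95 for interferon gamma, 0.41 for heat shock and, reversed, -0.069 for immediate early genes. Goblet-like medians were -1.10 for cholesterol synthesis, 0.087 for type I interferon and 0.16 for the unfolded protein response. Germinal centre B cell-like medians were 0.49 for heat shock and 0.087 for the unfolded protein response. Type I interferon medians were 0.79 in T cell-like and 1.06 in macrophage or monocyte-like cells. Mitochondrially encoded medians were -0.59 in fibroblast-like and -0.56 in macrophage or monocyte-like cells, and the immediate early median -0.076 in CD8 or intraepithelial T cell-like cells. Gene ratios with a reported interval excluding 1 that crossed 1 on thinning were Ptprq at 1.501 in colonocyte-like, Gpr39 at 1.77 in fibroblast-like, Ube2c at 1.06 in goblet-like, Pdia4 at 0.647 in germinal centre B cell-like, and Cst7 at 0.552 and Nrp1 at 1.21 in macrophage or monocyte-like cells.

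With clusters weighted alike, colonocyte-like medians were -0.17 for cholesterol synthesis, 0.96 for type I interferon and, reversed, -0.003 for MHC class II, and the ratio of Rbp2 was 0.987. Goblet-like medians were 0.34 for MHC class II, 0.38 for MHC class I, 0.55 for interferon gamma and -0.59 for cell cycle genes. Fibroblast-like medians were 0.17 for immediate early genes and 0.73 for heat shock. The immediate early median was -0.15 in CD8 or intraepithelial T cell-like cells, and the follicular helper median, reversed, -0.016 in T cell-like cells. Subtraction of free RNA gave -0.88 for colonocyte-like cell cycle genes, 2.004 for goblet-like MHC class II, -0.77 for T helper 17 genes in T cell-like cells, 0.00 for the immunoglobulin list in B cell-like cells and a ratio of 6.79 for Pigr there. Without a UMI minimum the T helper 17 median was -1.03 in T cell-like and, reversed, -0.035 in B cell-like cells. A minimum of 100 UMIs gave -0.87 for goblet-like cell cycle genes. DESeq2 size factors gave 0.18 for oxidative phosphorylation in B cell-like cells. As a mean over scaled cells Cdk1 stood at 1.23 in goblet-like cells. Counted by the most abundant class per cell, the plasma cell-like ratios were 0.896 for Igha, 3.29 for Ighm, 3.29 for Ighg2b and, reversed, 0.823 for Ighg1. The B cell-like ratios were 0.850 for Ighd, 0.629 for Ighg1, 0.680 for Ighg2b and 2.83 for Ighg3.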

Other observations

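Tests of the myeloid yield, of heat and dissociation stress and of small-intestinal epithelium were chosen only after the result was seen. So were Lars2, Cdk8, the genes named beside them and the adipocyte genes named here. Cells of fat and of the outer gut surface were more frequent in the RA library. A cluster of 45 RA and 0 butyrate cells was led by the adipocyte genes Cfd, Adipoq and Retn and took no class name. A count of 0 among 7703 cells allows a share of up to 0.0389%. Over all kept cells Cfd, the complement factor adipsin, had 66656 RA and 210 butyrate UMIs, and Adipoq, the hormone adiponectin, 2981 and 6. Mesothelial-like cells, which line the outer gut surface, numbered 24 and 3 (ratio 0.106, 0.0204 to 0.349), and 19 and 3 with the common UMI floor (0.120, 0.0227 to 0.4075). Other small classes depended on RA cells with few UMIs. Smooth muscle or pericyte-like cells numbered 14 and 3 (ratio 0.182, 0.0335 to 0.651) but 5 and 3 with the floor (0.456, 0.0708 to 2.34), and enteroendocrine-like cells 26 and 5 (0.163, 0.0489 to 0.431) but 7 and 5 (0.543, 0.136 to 1.99). Blood endothelial-like cells, at 86 and 75, were a larger part of the butyrate stroma, with a ratio of 2.03 within that compartment. Tuft-like cells, chemosensory cells of the epithelium, numbered 55 and 57.

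Although whole intestine is named in the labels, several abundant transcripts of small-intestinal enterocytes were nearly missing. In colonocyte-like cells the apolipoprotein gene Apoa4 had 0 UMIs in both libraries, Apoa1 and Fabp1 1 and 0, and the disaccharidase Sis 2 and 2, whereas Fabp2 had 7110 RA and 11171 butyrate UMIs. Lars2, a mitochondrial leucine tRNA synthetase, was lower in each of the 8 compared classes, with ratios from 0.291 to 0.817, and the Mediator kinase Cdk8 with ratios from 0.338 to 0.701. Other genes also went 1 way in all 8 classes. Some were lower, such as Camk1d (0.52 to 0.852), and some higher, such as B2m (1.14 to 2.25) and Hspe1 (1.17 to 2.41). Whether such uniform differences arose in the cells or in the making of the libraries was not tested. Epithelial barcodes made up much of those over the mitochondrial limit: the adhesion gene Epcam had a UMI in 82.4% of the 1536 butyrate and 54.2% of the 3037 RA barcodes over it, against 24.0% of the RA barcodes within it (median depths of 3939, 3065 and 4696 UMIs).

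The lower share of eosinophil-like cells may come from the higher lowest UMI number of the butyrate barcodes. With the floor of 2313 UMIs in both libraries the ratio was 2.85 (0.908 to 11.8), on 15 of 7703 butyrate and 4 of 5852 RA cells, so the lower share was no longer seen. A lower yield of myeloid cells as a whole stays open. Among myeloid cells with that floor the ratio was 4.39 (1.40 to 18.2), on 15 of 200 butyrate and 4 of 234 RA cells, which leaves no lower share to test. The naming of cells matters too: with each cell assigned on its own the ratio was 0.696, on 129 of 7703 butyrate and 157 of 6527 RA cells. A difference between the diets or the mice was not tested and stays open.

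The higher type I interferon genes of the butyrate library were seen in 6 of the 8 compared classes. After subtraction of free RNA the median stayed above the random range in 4 of the 4 non-epithelial classes tested, at 0.29 to 0.61. The subtracted profile was that of all kept cells, so this argues against free RNA of that make-up as the whole source. Free RNA richer in epithelial RNA was not tested and stays open. A different make-up of the colonocyte-like class was argued against by a median of 0.96 (random range -0.07 to 0.17) with clusters weighted alike. Heat and dissociation stress stays open. In 1 of the 6 classes, T cell-like cells, neither the heat shock nor the immediate early median was above its range (both inside, at -0.036 and 0.036), but members of both lists went both ways there. In B cell-like cells the heat shock median was below its range and the immediate early median above it, at 0.13 (range -0.14 to 0.05). Diet, disease state and the individual mouse coincide here and stay open, so an interferon response to any of them may underlie these values.

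The lower Reg3b and Reg3g of colonocyte-like cells could have followed from another mix of clusters. With clusters weighted alike the ratio of Reg3b was 0.0182 and that of Reg3g 0.0488. Within the clusters Reg3b had 39.1 against 1580.0 and 25.9 against 2440.0 CPM, so the mix of these clusters does not account for the lower values. A different mix of cells within a cluster was not tested and stays open. Reg3 genes are abundant in the small intestine, but more small-intestinal epithelium in the RA library is argued against as well, since the 6 measured enterocyte markers had a median log2 ratio of 0.03 (random range -0.35 to 0.23), with 3 of them higher, and Apoa4, Apoa1, Fabp1 and Sis had at most 2 RA UMIs each. The 10 RA cells with the most Reg3b held 59.5% of its UMIs, so a local response in the RA mouse stays open, as do diet and the part of the gut sampled.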
